A study of Mus musculus with 2 samples.

How the data were processed

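The samples were 2 libraries of total RNA from gastrocnemius of female hybrid mice at 36 days, 300 ng of RNA each, and the spike-in mixture was described for strand-specific, rRNA-reduced libraries, per the labels. Both libraries form 1 group. Replicate numbers came from the labels. The labels give the samples different numbers and a shared strain-level donor, and do not state whether they are separate animals.

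The authors deposited, for each library, a gene table, a transcript table derived from alignments to the transcriptome, and a transcript table derived directly from the reads. Expected counts and estimated counts are as deposited, are not normalised and need not be whole numbers. TPM values are as deposited and are transcripts scaled to a fixed total over all rows, with spike-ins included. The gene table also holds, per the file headers, a posterior SD of the count, used here as a score of how surely reads were assigned. The build was mm10 with GENCODE M21, per the deposited descriptions. The quantification program and its version are not given in the sources used here. Reads shared between near-identical genes are divided by estimation, so 7SL copies, nuclear copies of mitochondrial genes and pseudogenes are uncertain. The mice carry an allele set from another subspecies, and the effect of that on alignment to mm10 was not tested.

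The gene table had 81881 rows: 55536 genes, all named from the GENCODE M21 annotation, 97 spike-in rows and 26248 tRNA rows. The tRNA rows held 3 counts in replicate 1 and 0 in replicate 2 and were left out. Expected counts were rounded to whole numbers for edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A gene was detected at TPM of at least 1 in both libraries. Log2 ratios are replicate 2 over replicate 1, from CPM scaled by TMM with a prior count of 0.5. Ratios printed as folds are ratios of scaled counts.

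Before the data were examined, 31 gene lists with 398 distinct genes, 14 family shares and 30 alternatively spliced genes were fixed. Of the list genes, 395 had a row and 7 stand on more than 1 list. The genes named in the text follow a rule fixed then: the 20 highest genes outside mitochondrial and spike-in rows, up to 4 of the highest members of each list with low members where few, the genes of the family shares, the 10 largest log2 ratios in each direction at a mean count of at least 100, and the alternatively spliced genes. Actn2, Lmod2, Cox7a1, Sdhb, Lpl, Ucp3, Ckmt2, Pax7, Fos, Bhlhe40 and Arntl are list members outside that rule and were named after their values were seen. A further 4 lists (heart, thymocyte, mature B cell and more fat cell markers) were chosen after the earlier results were seen, and so were the members of them that are named. The values of 1 gene that the rule names are not reported here.

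With 2 libraries in 1 group no test of a condition was possible. Replicate spread was estimated by edgeR with an intercept-only design, after its filter on low counts. The number of genes over 2-fold apart was set beside 100 simulations of counting noise, and beside 100 simulations at the common coefficient of variation. List medians used members with a mean count of at least 10 and were set beside 10000 random lists matched on mean expression, which describes these libraries only. Counting intervals of ratios are exact (Clopper-Pearson) and intervals of shares are Wilson intervals at 95%. Intervals and the floor of 3 counts cover counting error only, because reads without molecular identifiers are not independent molecules.

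The steps were tested on simulated data. Coefficients of variation of 0.1, 0.2 and 0.3 were recovered as 0.0990, 0.199 and 0.298 over 14263 genes. With 200 of 9996 genes changed, 2.5-fold changes were recovered in 100% under counting noise and in 78.5% at a coefficient of variation of 0.220, where 341 unchanged genes also passed; 4-fold changes were recovered in 96.5% there. Of 100 random lists of 15 genes, 3 fell outside the middle 95%, and 100 of 100 did with a shift of 0.5. Their genes were drawn independently, so this does not cover lists of genes that vary together, whose medians may spread more. Alternatives covered detection thresholds, units, scaling, filters, pseudocount, the reads-based table and each library left out.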

Results

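Total RNA was sequenced from gastrocnemius, the large calf muscle, of female B6CASTF1/J mice, a first-generation hybrid of an inbred laboratory strain and a castaneus strain, at 36 days of age. The series holds 1 group of 2 libraries, replicate 1 and replicate 2, each made from 300 ng of RNA with synthetic spike-in RNAs added. There is no other condition, so the comparisons are between genes within the muscle, between the 2 libraries, and between 2 ways of quantifying transcripts. The gene tables held 37735687 estimated counts in replicate 1 and 40656175 in replicate 2. The labels number the tissue samples separately but do not state that they came from separate animals, so the spread between the libraries may be partly technical. Values are given per library or as mean ± SD with n = 2, where a wide SD shows libraries that lay apart. No group comparison exists and no p-value is given.

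The muscle expressed the contractile and energy genes of fast-twitch fibres at the top of its transcriptome. Outside mitochondrial and spike-in rows, the highest protein-coding gene was Acta1, skeletal actin, at 23912 ± 3532 TPM (SD, n = 2). It was followed by Ckm, the creatine kinase of muscle, at 19792 ± 4709 TPM and Mylpf, a light chain of fast myosin, at 18265 ± 5202 TPM. Tnnt3, fast troponin T, stood at 14948 ± 3062 TPM, Myh4, the 2B myosin heavy chain, at 12873 ± 3531 TPM, and Myl1, another fast light chain, at 12332 ± 3115 TPM. The calcium pump Atp2a1 reached 10896 ± 1988 TPM, the glycolytic enzyme Aldoa 10888 ± 2456 TPM and the calcium buffer Pvalb 8188 ± 2479 TPM. Tpm1, a tropomyosin, stood at 12150 ± 2607 TPM, Tnnc2 at 7652 ± 986 TPM, Tnni2 at 7645 ± 1048 TPM and Gapdh at 5191 ± 928 TPM. Acta1 (ENSMUSG00000031972.5) lies on chromosome 8 from 123891769 to 123894751 and Myh4 (ENSMUSG00000057003.12) on chromosome 11 from 67238029 to 67260446, in mm10 with GENCODE M21.

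By estimated counts, which do not correct for length, titin (Ttn) took the most reads, with 3854932 in replicate 1 and 4068168 in replicate 2. The 10 genes with the most counts held 39.5% of all counts (SD 0.0903 percentage points, n = 2). Non-coding RNA was abundant by alignment. Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle, were listed at an equal 154336 ± 22202 TPM each. Their reads were split between the copies, with a posterior SD of 22170 counts in replicate 1, so only their sum can be read. That sum was a mean of 4.98% of counts, or 30.9% of TPM, which corrects for length. Rn7sk, a regulator of transcription elongation, reached 13970 ± 276 TPM. The list of structural and regulatory non-coding RNAs had a median of 1103 TPM by alignment, against 35.3 TPM in the reads-based table. The level of this class of RNA therefore depended on the quantification. Spike-ins took 0.646% of counts in replicate 1 and 0.479% in replicate 2. At TPM of at least 1, 11264 genes were detected in replicate 1 and 11340 in replicate 2. Of these, 10828 were detected in both, 9955 of them protein-coding, while 436 passed in replicate 1 only and 512 in replicate 2 only.

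Mitochondrial genes took 9.39% of counts in replicate 1 and 17.5% in replicate 2. The mitochondrial rRNAs held 6.67% and 12.5%, and the 13 mitochondrial mRNAs 2.72% and 5.01%. The highest of these mRNAs was mt-Co1, a subunit of cytochrome oxidase, at 7992 TPM and 15453 TPM, followed by mt-Cytb at 4959.9 and 8998 TPM. A further 4 nuclear pseudogenes on chromosome 1 share reads with mitochondrial genes: Gm28661 (12653 ± 4668 TPM), Gm10925 (11028 ± 3832 TPM), Gm28437 (10159 ± 3668 TPM) and Gm29216 (5541 ± 2456 TPM). They are reported as uncertain, and they held 1.37% of counts in replicate 1 and 2.29% in replicate 2. Their higher values in replicate 2 went with those of the mitochondrial genes.

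Fibre type was read from shares of TPM within gene families. Myh4 held 98.2% of the TPM of the adult myosin heavy chains Myh1, Myh2, Myh4 and Myh7 in replicate 1 and 81.1% in replicate 2. Myh1, the 2X chain, held 0.842% and 9.57%, and Myh2, the 2A chain, 0.939% and 5.69%. Myh7, the slow chain, held 0.00153% in replicate 1 and 3.69% in replicate 2. Counting intervals did not overlap between the libraries: by counts, the 95% Wilson interval of the Myh4 share was 98.20% to 98.23% and 82.20% to 82.29%. These intervals do not cover the choice of quantification, which moved the shares by more than their width. In the reads-based table Myh4 held 97.4% of TPM in replicate 1 and 76.7% in replicate 2, and Myh7 held 0.0139% and 2.38%. Myh1 held 15.6% in replicate 2 there, while Myh2 differed less between the tables. The fast member also led the other fast and slow pairs in both libraries. Tnni2 held 99.99% of the troponin I pair in replicate 1 and 97.6% in replicate 2, Tnnc2 held 95.8% of the troponin C pair in replicate 2, and Atp2a1 held 97.8% of the calcium pump pair there. Ldha, the lactate dehydrogenase subunit common in fast muscle, held 99.9% of Ldha and Ldhb in replicate 1 and 88.1% in replicate 2.

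Shares of TPM were also taken for genes of muscle maturity. Myh3 and Myh8, the embryonic and neonatal myosins, together held 0.941% ± 0.130 of heavy chain TPM (SD, n = 2). Chrne, the adult subunit of the acetylcholine receptor, held 99.2% ± 0.192 of Chrne plus the fetal Chrng. Acta1 held 96.7% ± 1.72 of skeletal plus cardiac actin, Actc1, and Ckm held 99.98% of Ckm plus Ckb. Actc1 itself was 2.71-fold higher in the replicate 1 library (95% exact counting interval 2.66 to 2.75).

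**Figure D1:**
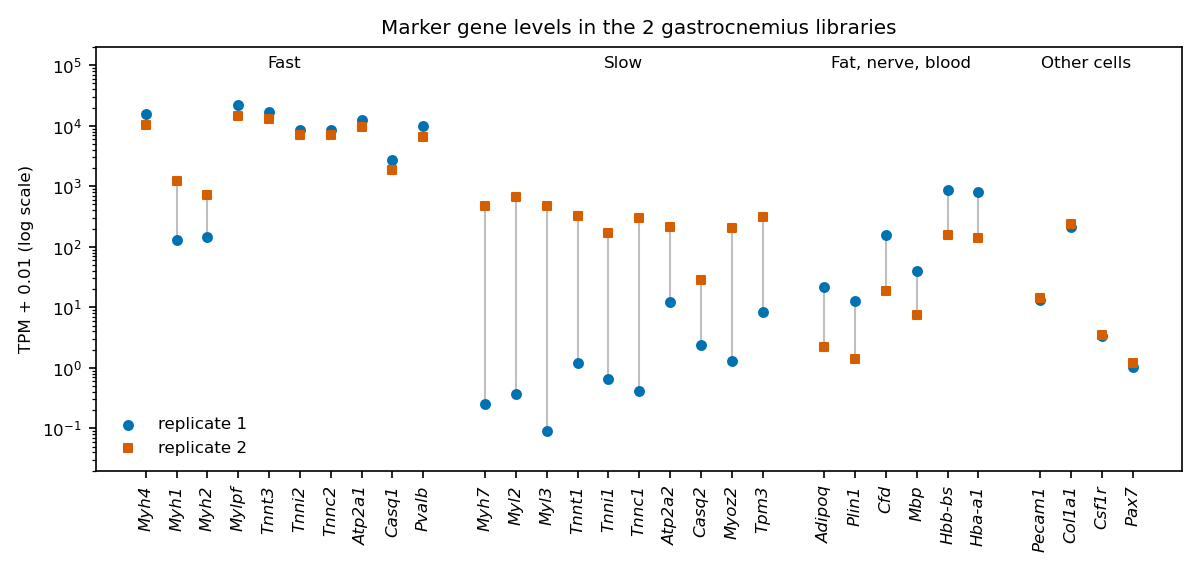
TPM plus 0.01 on a log axis for fibre type genes and cell type markers, with a circle for the replicate 1 library and a square for replicate 2, joined by a line. Slow-fibre genes such as Myh7 (0.24 and 472 TPM) lie far apart, while Pecam1 (13.2 and 14.2 TPM) and Col1a1 (212 and 237 TPM) lie close together.

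The lists of metabolic and contractile genes were detected in full, apart from the slow-fibre list. All 15 fast-fibre genes were detected in both libraries, with a median of 7393 ± 1354 TPM (SD, n = 2), and all 20 shared sarcomere genes, with a median of 558 ± 40.3 TPM. The 17 genes of glycogen breakdown and glycolysis had a median of 1009.7 ± 0.552 TPM, or 1608 TPM in the reads-based table. Their summed TPM, though, was 35856 in replicate 1 and 27606 in replicate 2. They were led by Aldoa, Gapdh, Pygm (glycogen phosphorylase) and Eno3. The 15 genes of excitation-contraction coupling had a median of 151 ± 23.4 TPM, led by Ryr1, the calcium release channel, at 812 and 715 TPM. The 23 nuclear-encoded respiratory chain genes had a median of 327 ± 63.9 TPM and the 17 genes of fatty acid oxidation 96.3 ± 35.5 TPM. Of the 15 slow-fibre genes, 7 were detected in both libraries and 8 in replicate 2 only. The 7 had a median of 2.35 TPM in replicate 1 and 215 TPM in replicate 2, and all 15 had a median of 0.65 and 215 TPM. The 7 creatine kinase and adenylate buffer genes had a median of 560.4 ± 99.6 TPM.

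Markers of other cell types ranged widely in level. The 6 red blood cell markers detected in both libraries had a median of 377 TPM in replicate 1 and 74.8 TPM in replicate 2. The 7 fat cell markers detected in both had 21.5 and 2.21 TPM. Over all members with a row the medians were 40.8 and 13.9 TPM for red blood cell markers and 8.66 and 1.27 TPM for fat cell markers. All 13 fibroblast markers were detected, with a median of 25.5 ± 0.368 TPM, led by the collagen genes Col1a1, Col1a2 and Col3a1. All 12 endothelial markers were detected, with a median of 8.16 ± 0.651 TPM, as were 10 of 11 pericyte and smooth muscle markers, with a median of 10.1 ± 2.97 TPM. Des, on that list, is also a muscle fibre gene. Of the macrophage markers 7 of 12 were detected, led by Lyz2 at 12.1 and 12.5 TPM. Of the tendon markers 9 of 10 were detected, led by Fmod at 27.7 and 34.1 TPM. Of the 15 satellite cell and myogenic genes 9 were detected in both libraries, with a median of 4.82 ± 0.544 TPM, or 3.09 TPM over all 15. Among them were Myf6 at 52.0 and 48.5 TPM and Pax7, the satellite cell factor, at 1.03 and 1.20 TPM. Of the neuromuscular junction genes 11 of 13 were detected, with a median of 7.90 ± 1.18 TPM. No neutrophil marker of 10 was detected in both libraries. Of the 12 lymphocyte markers only Ighm was, at 42.3 and 50.9 TPM. Embryonic and neonatal muscle genes, 9 of 10 detected, were led by Actc1 (1251 and 457 TPM) and H19 (896 and 906 TPM).

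Xist, the RNA of the inactive X chromosome, was measured at 18.4 TPM in replicate 1 and 14.4 TPM in replicate 2. The 4 Y-linked genes together had 0 counts in replicate 1, which allows up to 3 counts, and 2 counts in replicate 2. The reads-based table gave more for 2 of them, Uty (18.3 and 21.1 counts) and Kdm5d (13.5 and 22.8 counts), and the cause was not tested.

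The libraries agreed closely over most genes and differed in a distinct set. The Pearson correlation of log2(TPM + 1) over 55536 genes was 0.988 and the Spearman correlation 0.919. These are correlations across genes, which are not independent replicates. Among genes with a mean estimated count of at least 100, the median absolute log2 ratio was 0.17 and 87.9% of genes lay within 0.5. Over 44 spike-ins the Pearson correlation was 0.999. The common biological coefficient of variation from edgeR was 0.220 over 14263 genes. The counts differed beyond counting noise, with a chi-square of 181 per degree of freedom over 14996 genes.

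Slow-fibre genes led the genes higher in the replicate 2 library, with 4 of the 10 largest ratios on the slow-fibre list. Myl3, a light chain of slow myosin, had 2 counts in replicate 1 and 12566 in replicate 2, a ratio of 6019 (95% exact counting interval 1666 to 49703). Myl2, another slow light chain, was 2616-fold higher (1021 to 9602) and Myh7 was 2119-fold higher (1466 to 3190). These ratios were several times lower for Myl3 and Myh7, and lower for Myl2, in the reads-based table. Counts there were 7.0 and 12437 for Myl3, 9 and 11261 for Myl2, and 220 and 65027 for Myh7. Tnnc1, the troponin C of slow and cardiac muscle, was 969.9-fold higher (445 to 2644), and the muscle LIM protein gene Csrp3, with 3 counts in replicate 1, had a ratio of 574 (196 to 2788). Rag1, a recombinase of developing lymphocytes, had 0 counts in replicate 1 and 289 in replicate 2, at least 92.3-fold higher against a floor of 3 counts. Bdh1, a ketone body enzyme, had 1 count in replicate 1 and 727 in replicate 2, a ratio of 696 (125 to 27544). Reads-based counts also gave lower ratios for Tnnc1 (6.76 and 3834), Csrp3 (6 and 1525) and Bdh1 (2 and 698). Myh6, a myosin heavy chain, was 1023-fold higher (399 to 3755), with 11.9 and 3536 counts in the reads-based table. The pseudogenes Gm10163 and Rpl7a-ps11 completed the 10, and neither held in the reads-based table, where Gm10163 had 79.2 counts in replicate 1 and 10.9 in replicate 2.

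Of the 10 genes with the largest ratios in favour of the replicate 1 library, 5 were on the fat cell list. Pck1, an enzyme of glyceride and glucose synthesis, was 22.8-fold higher (95% exact counting interval 18.4 to 28.7). The hormone genes Lep (leptin) and Adipoq (adiponectin) were 14.6-fold and 8.95-fold higher. The fat droplet genes Cidec and Plin1 were 11.8-fold and 7.68-fold higher, and Cfd (adipsin) was 8.37-fold higher. The imprinted gene Nnat, with 379 and 10 counts, was 39.6-fold higher (21.3 to 83.2). Gm4841, Gm20425 and Pagr1a completed the 10. Gm20425 and Pagr1a carried a posterior SD of 43.0 and 47.7 counts in replicate 1 and are uncertain.

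Of 9996 genes with a mean estimated count of at least 100, 331 differed by more than 2-fold, 210 higher in replicate 2 and 121 higher in replicate 1. Counting noise alone gave 0 in each of 100 simulations. Noise at the common coefficient of variation, itself estimated from these libraries, gave a mean of 330.2, a number that the estimate largely fixes. Larger differences exceeded the simulated ones: 97 genes differed by more than 4-fold, against a simulated highest of 2, and 45 by more than 8-fold, against 0. Scaling to the spike-in total raised the median log2 ratio of all these genes by 0.38 and gave 519 genes higher in replicate 2 and 66 higher in replicate 1. Ratios below are relative to the TMM scaling.

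Of the 31 gene lists fixed before the data were examined, 20 had a median log2 ratio outside the range of matched random lists. A list needed at least 3 genes with a mean count of at least 10 to be counted. The neutrophil and Y-linked lists (0 genes) and Xist (1 gene) could therefore not be. All 15 slow-fibre genes were more than 2-fold higher in the replicate 2 library, with a median log2 ratio of 4.68, outside the middle 95% of matched random lists (-0.18 to 0.20). This median was 5.22 by TPM, 4.32 in the reads-based table and 7.29 over the 13 genes with a mean count of at least 100. Among them, Tnnt1, slow troponin T, stood at 1.19 and 321 TPM, Atp2a2, the slow calcium pump, at 12.2 and 215 TPM, and Tnni1 at 0.65 and 169.9 TPM. Atp2a2 differed less in the reads-based table. There Atp2a1 held 99.54% and 97.29% of the calcium pump pair, against 99.90% and 97.78% by alignment. Of the fast-fibre genes 13 of 15 were lower in replicate 2, with a median of -0.46, or -0.074 under spike-in scaling, where 9 of 15 were lower. The exceptions were Myh1, at a log2 ratio of 3.21, and Myh2, at 2.30. Genes of excitation-contraction coupling had a median of -0.24, lower for 14 of 15, and glycolysis genes -0.33, lower for 15 of 17. Spike-in scaling, which moves all genes alike, puts these medians at 0.15 and 0.054, still below the random range. The shared sarcomere list stayed within the random range at -0.05, although Actn2 (2.71) and Lmod2 (3.43) were higher in replicate 2.

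RNA of genes for oxidative metabolism was higher in the replicate 2 library. The 23 nuclear-encoded respiratory chain genes were all higher, with a median log2 ratio of 0.48, and the 13 mitochondrial mRNAs were all higher, with a median of 0.91. Among the nuclear-encoded genes, Cox7a1 and Sdhb, subunits of cytochrome oxidase and of succinate dehydrogenase, had log2 ratios of 0.86 and 0.77. Both lay above the median of that list. Genes of fatty acid uptake and oxidation were higher for 16 of 17, with a median of 0.83. Fabp3, a fatty acid carrier, stood at 63.0 and 375 TPM and Lpl, lipoprotein lipase, at 42.0 and 158 TPM. Ucp3 was the exception, at -0.25. The creatine kinase and adenylate list had a median of -0.29, with a sign change to 0.096 under spike-in scaling, and it held both Ckm at -0.51 and the mitochondrial Ckmt2 at 1.43.

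Among cell type markers, fat, nerve and red blood cell genes were higher in the replicate 1 library. The fat cell list had a median log2 ratio of -2.94 over 11 genes, 9 of them lower in replicate 2, the nerve list -1.39 over 12, and the red blood cell list -2.53 over 8. The myelin gene Mbp, on the nerve list, stood at 39.2 and 7.57 TPM. The globin genes Hbb-bs (865 and 156 TPM) and Hba-a1 (815 and 137 TPM) led the red blood cell list. The exceptions on the fat list were Cidea, with 4 and 29 counts and a log2 ratio of 2.65, and Car3, which is also abundant in muscle, at 0.27. Lymphocyte markers were higher in replicate 2, with a median of 5.14 over 6 genes, or 4.67 with genes at 0 counts set at the floor. Their median was 3.59 in the reads-based table and 3.64 with no filter on low counts, where 9 of 11 genes were higher. Cd8a had 1 and 123 counts and Cd4 had 3 and 85 counts, ratios of 118 (20.8 to 4691) and 27.1 (8.98 to 134). Tendon markers were higher in replicate 2 for 10 of 10, with a median of 0.70. Endothelial (0.10), fibroblast (0.13), pericyte (0.01) and macrophage (0.06) medians stayed within the random range, as did neuromuscular junction genes (-0.10). Satellite cell and myogenic genes had a median of 0.23, which fell within the random range in the reads-based table (0.21) and with no filter on low counts (0.09). Embryonic and neonatal genes had a median of -0.30, or 0.085 under spike-in scaling, and -0.08 within the random range at a mean count of at least 100. No neutrophil or Y-linked gene had enough counts by alignment.

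**Figure D2:**
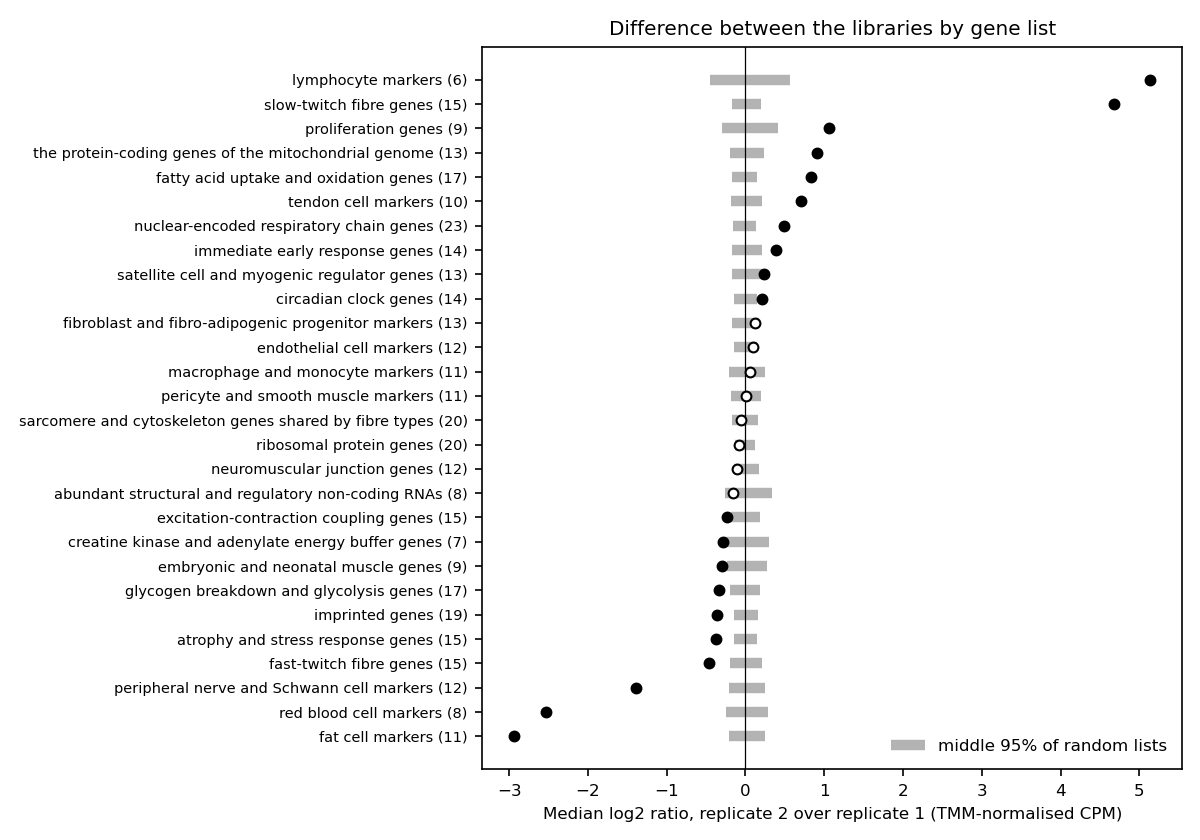
Median log2 ratio of replicate 2 over replicate 1 per gene list, from TMM-normalised CPM, with the number of genes in brackets. Filled points lie outside the grey bar, the middle 95% of 10000 random lists matched on mean expression, and open points lie within it; slow-fibre genes stand at 4.68 and fat cell markers at -2.94. Under spike-in scaling all medians and bars move up alike by about 0.38; 6 negative medians outside the bar and the negative ones within it change sign, and each list keeps its place against the bar.

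Transcript choice was more alike between the libraries than between the quantification methods. Of 5540 genes with gene TPM of at least 5 and at least 2 transcripts, 91.5% had the same most abundant transcript in both libraries in the alignment-based table (95% Wilson interval 90.8% to 92.2%) and 88.1% in the reads-based table. Between the tables of a single library, 74.3% matched in replicate 1 (73.2% to 75.5%) and 74.4% in replicate 2 (73.3% to 75.6%).

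Among 30 alternatively spliced muscle genes, 24 had the same leading transcript in both libraries by alignment, 25 by the reads-based table, and 19 in all 4 tables. The share of the leading transcript differed by a median of 1.64 percentage points between the libraries and 7.98 between the tables. Stable cases included Atp2a1-201 (99.8% ± 0.174 of gene TPM, SD, n = 2), Capn3-202 of a muscle protease (94.8% ± 0.0483) and Dmd-203 of dystrophin (63.0% ± 1.16). Tpm1-205 held 97.3% ± 0.340 by alignment and 75.4% ± 1.16 in the reads-based table. Myl1-202 held 73.6% ± 1.48 by alignment, whereas Myl1-207 led in the reads-based table with 39.2% and 31.8%.

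Some genes had a different leading transcript, by share, in the 2 libraries. Tpm3, a tropomyosin on the slow-fibre list, was led by Tpm3-201 in replicate 1 (45.1%) and by Tpm3-205 in replicate 2 (95.5%), and the reads-based table gave the same pair of leaders. Tpm3-205 spans 90072649 to 90092130 on chromosome 3 and held 10.3% in replicate 1. By alignment Tpm3-201 stood at 3.77 TPM in replicate 1 and 4.08 TPM in replicate 2, and Tpm3-205 at 0.86 and 298.85 TPM. The change of leader thus came from more Tpm3-205, with Tpm3-201 at a similar level. Tnnt3 was led by Tnnt3-224 in replicate 1 (54.6%) and by Tnnt3-201 in replicate 2 (47.7%), but the reads-based table put Tnnt3-225 first in replicate 2. Fhl1, Camk2d and Neb changed leader by alignment and not in the reads-based table, and Pkm and Mbnl2 did so in the reads-based table only. Several of these leads were narrow: by alignment in replicate 1, Neb-204 held 21.6% against 21.2% for Neb-202, and Fhl1-201 held 41.4% against 40.03% for Fhl1-204. In the reads-based table Pkm-201 led Pkm-202 in replicate 1 by 47.8% to 45.6%, and Mbnl2-201 led Mbnl2-204 in replicate 2 by 39.6% to 38.8%. Tnnt1 rested on 31 counts in replicate 1, too few to rank its transcripts.

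**Figure D3:**
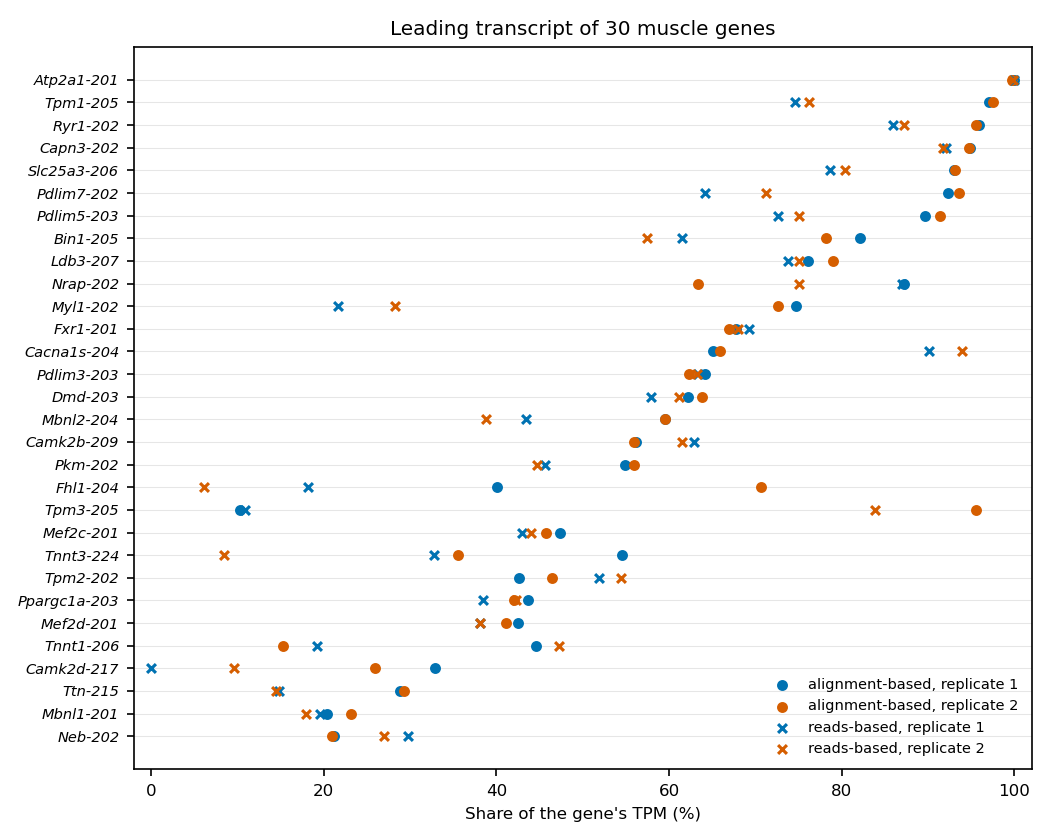
Share of gene TPM, in percent, held by the leading transcript of 30 muscle genes in each library, with circles for the alignment-based and crosses for the reads-based table. Tpm3-205 separates by library (10.3% and 95.5% by alignment), while Tpm1-205 separates by table (97.3% and 75.4%).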

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

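The 4-fold limit, the counts without list members, the agreement without slow-fibre genes, the floor at 0 counts and the nuclear copies of mitochondrial genes were chosen after seeing the data. No paired analysis was possible because there is 1 group. Leaving out a library of 2 moves a mean by less than 1 SD by arithmetic, so it says nothing of stability; the ranges are 11264 to 11340 detected genes, 9.39% to 17.5% mitochondrial counts and 81.1% to 98.2% for the Myh4 share. That SD is wide for Myh4, which stood at 90.2% by counts and 87.0% in the reads-based table, against a mean of 89.6%.

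Detected genes numbered 11687 in the reads-based table, 14331 at 10 counts, 15927 at TPM of at least 0.1 and 6265 at 5, a stricter limit that passes fewer genes. The Pearson correlation was 0.984 with a pseudocount of 0.1, 0.976 with genes at TPM of at least 1 and 0.989 without the slow-fibre list. The coefficient of variation ranged from 0.218 to 0.260. Genes over 2-fold apart numbered 335 with DESeq2 size factors, 342 by TPM, 341 in the reads-based table and 269 without the list members. They numbered 585 under the spike-in total, 1164 at a mean count of at least 10, 157 at 500 and 97 at 4-fold, where the filters and the limit change what is counted. The excess under spike-in scaling went with the shift of 0.38 in all genes.

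Of the fixed lists 20 lay outside the random range, and 18 to 20 did in each alternative. DESeq2 and spike-in scaling move all genes and the random range alike, so every list kept its place against that range. These 2 alternatives therefore had to return 20. The upward shift under spike-in scaling changed the sign of the negative medians within the range and of 6 below it. Those 6 became coupling 0.15, glycolysis 0.054, creatine kinase 0.096, embryonic 0.085, stress 0.0074 and imprinted 0.022. The same leading transcript in both libraries was found in 87.4% at gene TPM of at least 1 and 94.4% at 20. It was found in 99.4% where the leading transcript held at least 60% by alignment in replicate 1. That last limit was set on a library that is itself compared, which favours agreement. Between tables the share was 72.1% and 72.5% at 20, and 84.9% and 84.7% at 60%, in replicates 1 and 2; the cause was not tested. Shares of the leading transcript moved by more than the spread between libraries in 25 of 30 genes in the reads-based table. Median TPM moved by at least that spread in 23 lists there and not in 6. Rescaling TPM without mitochondrial and spike-in rows moved 18 medians and left 10. Taking all members moved 9 and left 20. Depth limits genes with few counts in a library, such as Tnnt1 and Myl3 in replicate 1.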

Other observations

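Several regulatory gene lists also differed between the libraries. Immediate early genes were higher in the replicate 2 library for 11 of 14, with a median log2 ratio of 0.39. Btg2 stood at 8.16 and 21.5 TPM, Fos at 2.20 and 5.36 TPM and Dusp1, a phosphatase induced by stress, at 25.3 and 43.8 TPM. Circadian clock genes had a median of 0.21, with Dbp at 35.0 and 46.4 TPM, Bhlhe40 at 21.9 and 41.5 TPM and Arntl, the core activator, at 5.61 and 4.16 TPM. Proliferation genes had a median of 1.06 over 9 genes, led by Top2a with 31 and 174 counts. Lymphocyte and thymocyte markers, with medians of 5.14 and 5.39, or 4.67 and 4.07 with genes at 0 counts set at the floor, were higher in the same library. Imprinted genes were lower in replicate 2 for 16 of 19, with a median of -0.36, or 0.022 under spike-in scaling, and included Igf2 (82.3 and 34.1 TPM) and Cdkn1c (40.1 and 16.9 TPM). Atrophy and stress genes had a median of -0.38 and a mean of 0.02, with Trim63, a muscle ubiquitin ligase, at 157 and 94.5 TPM and the small heat shock gene Hspb7 at 16.0 and 144 TPM. Their median was 0.0074 under spike-in scaling. Ribosomal protein genes (-0.08) and structural non-coding RNAs (-0.15) stayed within the random range.

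The tests of the fibre pattern by scaling and of the fat pattern by a lower share of fibres were chosen after their results had been seen, as was the widening of the fibre pattern from mitochondrial to slow-fibre genes. The lists for heart, thymocytes, B cells and more fat cells were written after the patterns and before their own values were seen. The samples share their labelled group, so no biological explanation from the design was tested.

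Slow-fibre and mitochondrial RNA was higher in the replicate 2 library. Heart RNA is argued against, since the highest of 12 heart markers reached 0.25 TPM in replicate 2, although Myh6, a heart myosin gene not on that list, stood at 0.17 and 96.6 TPM. For slow-fibre genes scaling is argued against, since their lowest median under the other scalings was 4.69. DESeq2 and spike-in scaling move all genes alike, so this test had little room to come out otherwise. No limit was set for mitochondrial mRNAs, whose median was 0.92 with DESeq2 size factors, 1.29 under the spike-in total and 0.89 by TPM. A larger part of oxidative fibres in the replicate 2 sample may account for the pattern. Nuclear-encoded respiratory chain genes had a median log2 ratio of 0.48, above the limit of 0.46. That limit was set in advance as 0.5 times the median of the mitochondrial mRNAs, 0.91. Whether the region of muscle taken or the animal differed remains open.

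RNA of Rag1 and of lymphocyte markers such as Cd4 and Cd8a was higher in the replicate 2 library. Of 12 thymocyte markers, 8 were at least 3-fold higher against a floor of 3 counts, the number set in advance, so thymocyte RNA in that library may account for it. Dntt had 0 and 52 counts, Lck 0 and 79 and Themis 0 and 72, but Ptcra had 0 in both, and Satb1 (31.4 and 35.3 TPM) and Arpp21 (3.57 and 9.59 TPM) were detected in both libraries. Lymph node or blood RNA that holds B cells is argued against, since mature B cell markers summed to 0.483% of the thymocyte markers there, or 2.91% without Satb1 and Arpp21, a version chosen after seeing the data, although the B cell gene Ighm, not in that sum, stood at 42.3 and 50.9 TPM in the libraries. Mature T cells without B cells remain open as a source of the Cd4 and Cd8a RNA, although Rag1 (0 and 289 counts) is a gene of developing lymphocytes. How such RNA entered the library also remains open.

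Fat cell, nerve and red blood cell RNA was higher in the replicate 1 library. A lower share of muscle fibre RNA is argued against, since the lower of the endothelial and fibroblast medians was 0.10. More fat tissue in the replicate 1 sample may account for the fat cell part, as 12 further fat cell markers, 9 of them detected in both libraries, had a median log2 ratio of -1.20. That median also passed the limit of -1 set in advance in the reads-based table (-1.44), with DESeq2 size factors (-1.19) and by TPM (-1.16). The explanation remains open, since the median was -0.65 over the 6 genes with a mean count of at least 100. Under spike-in scaling, which moves all genes alike, it was -0.81. Both of these values were short of the limit. Dgat2 (5.15 and 27.5 TPM) and Aqp7 (3.91 and 4.22 TPM) also went the other way. The nerve and red blood cell parts were not tested.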
